A study of Mus musculus with 18 samples.

How the data were processed

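The libraries held polyadenylated RNA of mouse embryonic stem cells, 18 in all, in 6 groups of 3: wild type, a conditional BAP1 knockout line without and with 4-hydroxytamoxifen, a C91A knock-in line without and with 4-hydroxytamoxifen, and an RNF2-BAP1 double knockout with the drug. Per the labels the drug was given at 100 nM for 4 days and all cells received emricasan; whether the wild type received the drug is not given in the sources used here. Replicates carry no numbers in the labels, so they were numbered in the order of submission and pair nothing. Per the labels RNA was isolated with RNeasy kits, libraries were made with TruSeq version 2 reagents and sequenced on a HiSeq instrument as single reads of 50 bases, with 30 M (mega) reads planned per sample. Whether read strand was used in counting is not given in the sources used here.

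Per the submitters' processing notes, reads were aligned with GSNAP (version not given) to GRCm38. Each deposited sample file gave for each gene, by Entrez identifier, a count, the number of uniquely aligned reads per gene model, and a size-factor-adjusted RPKM, both computed by the authors. The deposited counts were the values analysed, in counts per gene. The deposited RPKM values were used only to recover the authors' size factors from the ratio of RPKM to count, which was constant within each library to a relative deviation of at most 3.4e-14. How the authors computed those factors is not given in the sources used here. Each file listed 36528 genes, of which 31049 were named from the RefSeq table of GRCm38.p6 and 78 from GENCODE M21, and 5401 had no name there; named genes held 97.89% to 98.11% of the counts of each library. Counts of 9236 genes were 0 in every library.

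In megacounts (M), libraries held 8.11 to 23.0 M counts, with group means of 20.4 (wild type), 20.4 (untreated knockout line), 12.7 (BAP1 knockout; 12.1, 8.11 and 18.0), 17.5 (untreated C91A line), 16.4 (C91A mutant) and 16.8 M (double knockout). Counts of each pair of libraries of a group differed by more than sampling alone gives (chi-square per degree of freedom 1.77 to 5.78), so no library repeated another. The common dispersion was 0.002, a coefficient of variation of 4.5% between replicates, which is low for separate cultures and makes small changes pass the test.

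Genes were filtered with filterByExpr on the groups, leaving 16875, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with 1 mean per group, all 18 libraries sharing the estimate of spread, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors are the log2 fold change divided by the square root of its F statistic. The 7 comparisons were knockout and C91A mutant each against its untreated line, the difference of these 2 effects, double knockout against knockout and against wild type, and each untreated line against wild type. Under any scaling tried, the median change of all genes was at most 0.035 in the comparison of double knockout with knockout. Overlaps of called genes are given beside the product of the 2 counts divided by the genes tested. For the 2 comparisons that share the knockout libraries, 20 data sets with no change between groups were simulated and tested in the same way.

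The groups of genes were 30 lists fixed before the data were examined: survival and pro-apoptotic BCL2 family genes, caspases and death receptor genes, p53 targets, general and naive pluripotency, formative epiblast, endoderm, mesoderm, neuroectoderm, trophoblast, HOX clusters, PRC1, PRC2, the BAP1 complex with other H2A deubiquitinases, two-cell-like, germline and imprinted genes, cholesterol synthesis, glycolysis and hypoxia, the ATF4 response, endoplasmic reticulum chaperones, replication, mitosis, interferon-stimulated genes, fibroblast markers (for feeder cells), ribosomal proteins, mitochondrially encoded genes, histones, and MAPK feedback with immediate early genes. Each was tested with camera on log2 CPM (prior count 2, preset correlation 0.01), 2-sided, with adjustment over the 29 lists with at least 5 tested members; the survival list had 4 and was not tested as a set. An estimated correlation and fry were run as checks. Camera compares a list with all other genes, so a list can pass while most of its members change little. Where a call with the preset correlation was lost with the estimated one, some lists are given with the latter p alone.

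The genes named were also set by a rule written before the data were examined. It took Bap1, Rnf2, Bcl2 and Mcl1, the 5 highest and 5 lowest genes of the main comparisons (3 and 3 for the difference of the 2 effects and for double knockout against wild type) with a mean log2 CPM of at least 2 and, except for the difference, groups whose ranges did not overlap, which chance alone gives for 10% of genes. It further took up to 3 members of each list that passed or had at least 1 in 3 tested members called, and all called BCL2 family members. It gave 258 genes, of which 102 overlap another annotated gene; reads of such pairs, and of genes with near-identical copies (two-cell-like genes, histones, ribosomal proteins, H2-K2), cannot be assigned with certainty. A few genes from the lists are not reported here. On GRCm38, Bap1 lies at chr14 31251352 to 31259930, Rnf2 at chr1 151469398 to 151500991, Bcl2 at chr1 106538176 to 106714290 and Mcl1 at chr3 95656944 to 95663179.

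The alternatives were size factors of the DESeq2 type, no filter on low counts (27292 genes), DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, a test against a minimum fold of 1.5, and leaving out each library in turn. The authors' size factors and thinning every library to 8.11 M counts were added after the data were seen. The pipeline was tested on simulated data with the depths of these libraries. In the comparison of knockout with control, edgeR recovered 44 of 64 genes changed 1.5-fold (68.8%), 64 of 70 changed 2-fold (91.4%) and 65 of 66 changed 4-fold (98.5%), with 10 false calls (5.5% of its calls), and called 0 genes in a comparison where nothing had been changed (5.1% at an unadjusted p under 0.05). Tables and plots were made with Python 3.11.15 and scipy 1.17.1. The RPKM values were left out of the tests because they are scaled versions of the counts.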

Results

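BAP1 is a deubiquitinase that removes ubiquitin from histone H2A, and RNF2 is a ligase that adds it. Mouse embryonic stem cells lacking BAP1, carrying the inactive C91A form of BAP1, or lacking both BAP1 and RNF2 were compared with untreated cells of the same lines or with wild type, at day 4 and with 3 libraries per group. All cells also received emricasan, which blocks caspases, so transcript levels were read in cells protected from caspase-dependent death. The labels do not say whether the replicates were separate cultures, so each p-value measures only the spread between these libraries. The knockout and C91A controls lacked 4-hydroxytamoxifen, so the effect of each allele includes that of the drug and of Cre. Levels are CPM, the counts scaled by the library total and the TMM factor (mean and SD of 3 libraries). Changes are log2 fold changes with their standard error (SE). Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16875 genes.

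Bap1 transcripts were measured at 178 CPM (SD 6.64) in wild type, 169 (SD 1.53) in the untreated knockout line, and 150 (SD 2.30) after knockout. They stood at 88.9 (SD 4.57) in the untreated C91A line, 165 (SD 1.66) in the C91A mutant and 153 (SD 11.7) in the double knockout. The gene fell slightly after knockout (-0.17, SE 0.05, adjusted p = 0.0027) and rose in the C91A mutant (0.89, SE 0.05, adjusted p = 8.3e-19). The double knockout stood at 0.03 (SE 0.05, adjusted p = 0.67) against the knockout. Rnf2 was measured at 115 CPM (SD 7.49) in wild type, 112 (SD 2.02) and 103 (SD 6.54) in the untreated knockout and C91A lines, 111 (SD 9.77) in the C91A mutant and 74.5 (SD 3.52) in the double knockout. The 3 knockout libraries stood at 114.3, 127.4 and 127.5 CPM. Rnf2 fell in the double knockout against the knockout (-0.73, SE 0.06, adjusted p = 1.5e-13) and against wild type (-0.63, SE 0.06, adjusted p = 6.1e-12). Counts over a whole gene include transcripts that lack deleted exons or carry a point mutation, so these levels check the genotypes only in part. The small difference of Rnf2 between BAP1 knockout and its control (0.14, SE 0.06, adjusted p = 0.037) lost its call with DESeq2 (0.14), with no filter on low counts (0.12), without replicate 1 (0.13) or 3 (0.13) of the control, and without replicate 2 (0.12) or 3 (0.11) of the knockout.

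**Figure D1:**
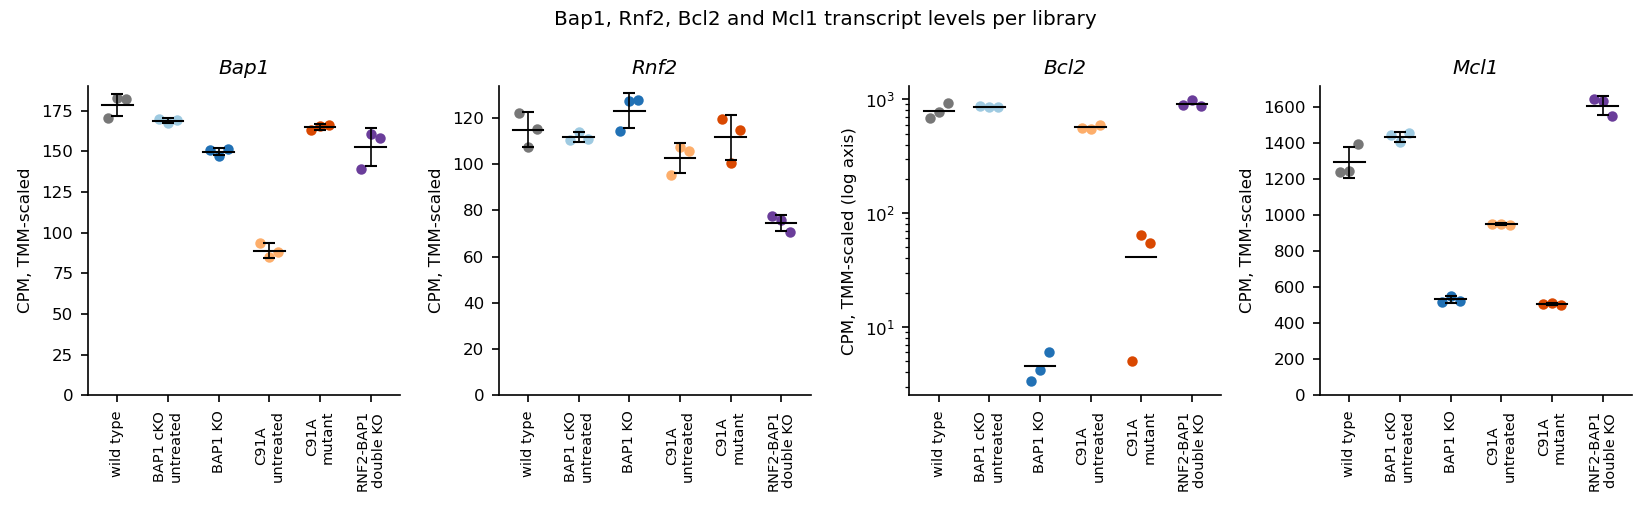
Expression of Bap1, Rnf2, Bcl2 and Mcl1 in CPM (Bcl2 on a log axis) in the 6 groups; dots are the 3 libraries, the line is their mean and bars are 1 SD, except for Bcl2, which has no bars. Bcl2 stands at 861 CPM in the untreated knockout line, 4.53 after BAP1 knockout, 41.3 in the C91A mutant and 918 in the double knockout.

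Bcl2, which blocks mitochondrial apoptosis, showed the deepest fall after BAP1 knockout of all genes named here, from 861 CPM (SD 18) in the untreated line to 4.53 (SD 1.37), a log2 fold change of -7.50 (SE 0.33, adjusted p = 1.7e-22). Mcl1, a second survival protein of the family, fell from 1436 CPM (SD 26.9) to 533 (SD 18.6), or by -1.43 (SE 0.04, adjusted p = 1.4e-28). The other 2 tested survival members rose, Bcl2l1 (which encodes BCL-XL) by 0.63 (SE 0.06) and Bcl2l2 by 0.25 (SE 0.07). Among 11 tested pro-apoptotic members, 3 rose (Bbc3 0.89, Pmaip1 0.86 and Bax 0.53), 5 fell (Bik -0.83, Bad -0.54, Bok -0.42, Bcl2l11 -0.36 and Bid -0.23) and 3 did not pass the test. As a set they did not differ from other genes (adjusted p = 0.966). Nor did 22 caspase and death receptor genes (adjusted p = 0.606), of which 8 rose and 10 fell (8 and 11 adjusted over the list alone), including Ripk3 (-2.02), a kinase of necroptosis, and Ripk1 (-1.10). The fall of Bik was lost without replicate 3 of the knockout (-0.64).

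**Figure D2:**
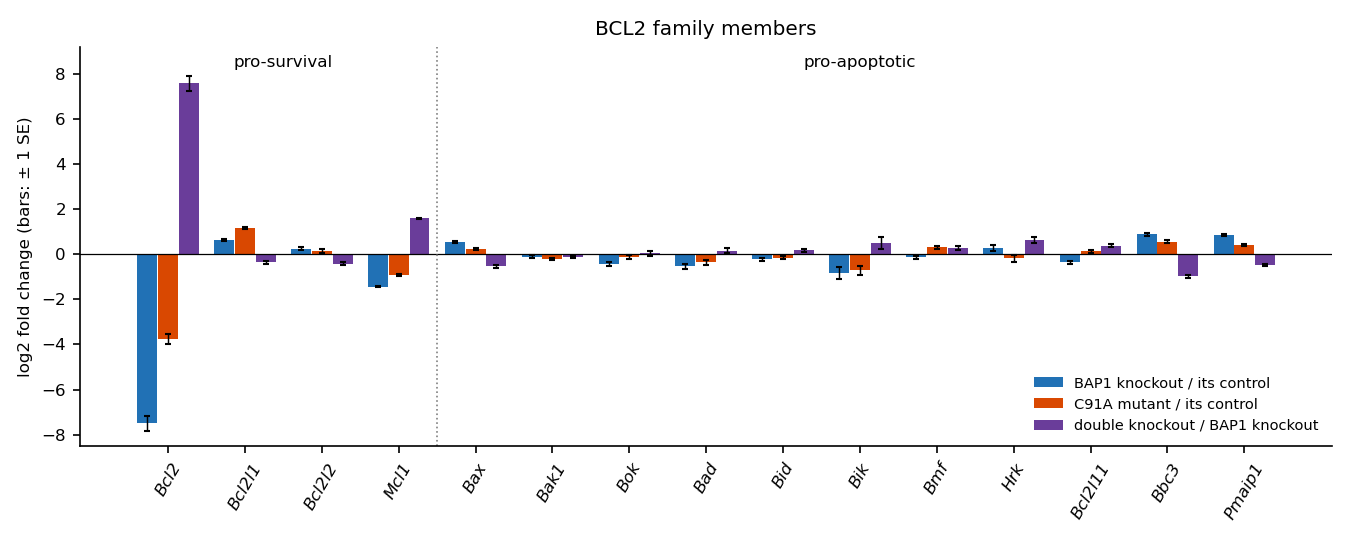
Log2 fold changes of 4 pro-survival and 11 pro-apoptotic BCL2 family genes in BAP1 knockout against its control, C91A mutant against its control, and double knockout against BAP1 knockout; bars are 1 SE. Bcl2 lies at -7.50, -3.76 and 7.59 and Mcl1 at -1.43, -0.91 and 1.59.

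After BAP1 knockout, 5283 of 16875 genes were higher and 5109 lower than in the untreated line, and 812 and 1771 of them changed at least 2-fold, so large changes were more often falls. Rankings here and below are among genes with a mean log2 CPM of at least 2. The lowest named genes after Bcl2 were Igsf23 (-4.91, SE 0.37), Zbtb32 (-4.15, SE 0.15), Inhbb (-4.11, SE 0.15), which encodes a subunit of activin B, and the noncoding RNA Halr1 (-3.89, SE 0.18). The highest were the actin genes Acta1 (3.25, SE 0.14) and Acta2 (3.22, SE 0.09), the homeobox gene Lhx9 (2.88, SE 0.16), Tgfb2 (2.70, SE 0.20), a growth factor, and Cdh2 (2.63, SE 0.10), which encodes N-cadherin. Acta2 went from 4.81 to 44.9 CPM, Lhx9 from 2.30 to 17.4 and Cdh2 from 5.05 to 31.2, while Zbtb32 went from 29.4 to 1.72. At an unadjusted p under 0.05, 10985 genes differed, and the adjusted calls took 61.6% of those tested.

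General and naive pluripotency genes mostly fell after BAP1 knockout. Of 16 general pluripotency genes none rose and 14 fell (adjusted p = 3.12e-06, and 0.00422 with an estimated correlation, written below as estimated). Examples were Tdgf1 (-0.98), Utf1 (-1.10) and Foxd3 (-3.61), a forkhead factor of early embryos. Of 20 naive pluripotency genes 14 fell and 6 rose (adjusted p = 0.0036, 0.0229 estimated), with Fgf4 at -1.16, Nr0b1 at -1.53 and Gbx2 at -2.59. The untreated knockout line was above wild type for 17 of these 20 genes (2 below, median 0.65) and for 11 of the 16 general genes (2 below, median 0.2). After knockout Nr0b1 was below wild type (34.44 against 49.21 CPM) and Nr5a2 was not (26.61 against 23.56). The lists were not tested between knockout and wild type. In the opposite direction, 15 of 22 primitive and visceral endoderm genes rose and 1 fell (adjusted p = 0.000101, 0.0229 estimated), among them the endocytic receptor Lrp2 (1.52) and the basement membrane collagens Col4a1 (1.08) and Col4a2 (1.14). The untreated knockout line stood below wild type for 18 of these 22 genes (median -1.28). After knockout Col4a1 was at 186.5 CPM against 427.1 in wild type, Col4a2 at 123.9 against 237.1, and Lrp2 at 211.8 against 105.3. Of 17 formative genes 5 rose and 9 fell (Tcf15 -2.55, adjusted p = 0.14). Of 19 mesoderm genes 7 rose and 7 fell (Wnt3 1.48, adjusted p = 0.966), and of 18 trophoblast genes 6 rose and 5 fell (Krt18 1.01, adjusted p = 0.722). The 20 neuroectoderm genes, with 12 up and 2 down (Ncam1 1.44, Stmn2 0.83), passed the preset test at adjusted p = 0.0137 but had adjusted p = 0.0974 with an estimated correlation.

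Targets of p53, which drive arrest and cell death, rose after BAP1 knockout in 24 of 32 cases and fell in 1 (24 and 3 adjusted over the list alone, adjusted p = 2.54e-09, 0.00267 estimated). Examples were Perp (1.04), Plk2 (0.89) and Ercc5 (0.89). Of 21 genes typical of fibroblasts 15 rose and 1 fell (adjusted p = 4.43e-07, 0.00422 estimated). They were led by Acta2, Tagln (2.28), both parts of the contractile cytoskeleton, and Thbs1 (1.92), a secreted matrix protein. Imprinted genes rose in 16 of 30 cases and fell in 5 (adjusted p = 0.0108, 0.0283 estimated), with Gnas at 0.98 and Grb10 at 0.95. Glycolysis and hypoxia genes fell in 18 of 28 cases and rose in 2 (adjusted p = 2.9e-05, 0.048 estimated), with Pdk1 at -1.76 and Pfkm at -1.38. Interferon-stimulated genes fell in 12 of 24 cases and rose in 1 (adjusted p = 0.0022, 0.0195 estimated), with the RNA sensor gene Ddx58 at -1.72 and Parp14 at -3.01.

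Several other groups differed from other genes after BAP1 knockout under the preset correlation but not the estimated one. Of 82 ribosomal protein genes 63 rose and 3 fell (65 and 3 adjusted over the list alone), such as Rps20 (0.93) and Rps3 (0.50). The list had adjusted p = 2.54e-09, and adjusted p = 0.106 with an estimated correlation. Of 27 germline genes 19 fell and 3 rose (Piwil2 -1.69, adjusted p = 0.000866, and adjusted p = 0.126 with an estimated correlation). MAPK feedback genes fell in 14 of 23 cases and rose in 6 (Spry4 -2.42, adjusted p = 0.0014, and adjusted p = 0.126 with an estimated correlation). Among lists that did not pass were 28 genes of PRC1, the complex that holds RNF2 (14 up, 5 down, adjusted p = 0.18). The others were 11 genes of PRC2 (2 up, 6 down, Jarid2 -0.70, adjusted p = 0.326) and 17 of the BAP1 complex and H2A deubiquitinases (9 up, 5 down, Mbd6, which overlaps Ddit3, 1.22, adjusted p = 0.221). Of 35 HOX genes 9 rose and 2 fell (8 and 1 over the list alone, adjusted p = 0.579), and of 18 two-cell-like genes 1 rose (adjusted p = 0.645).

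Also not past the test after knockout were 25 genes of cholesterol synthesis (4 up, 12 down, adjusted p = 0.0575). There were also 28 of the ATF4 stress response (11 up, 10 down, Ddit3 1.09, adjusted p = 0.656) and 19 endoplasmic reticulum chaperones (7 up, 4 down, Canx 0.49, adjusted p = 0.637). Of 26 replication genes 4 rose and 10 fell (Ccne1, a cyclin of S phase entry, -1.27, adjusted p = 0.155), and of 26 mitotic genes 11 rose and 2 fell (Nusap1 0.62, adjusted p = 0.0763). Of 11 mitochondrially encoded genes 5 rose (COX1 0.71, adjusted p = 0.147) and of 9 histone genes 4 rose (H4c9 0.81, adjusted p = 0.221). In total 12 of 29 lists passed with the preset correlation (14 unadjusted) and 8 with the estimated one, and fry, which asks whether a list's genes move one way without comparing them with other genes, called 24. Counts adjusted over the list alone were equal unless given.

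The C91A mutant, whose BAP1 keeps its sequence except for the catalytic cysteine, changed in much the same direction. Bcl2 fell from 568 CPM (SD 25.9) to 41.3 (SD 31.8), or by -3.76 (SE 0.23, adjusted p = 1.9e-17), and its 3 mutant libraries stood at 0.89%, 11.27% and 9.67% of the control level. Mcl1 fell from 950 CPM (SD 5.07) to 507 (SD 6.87), or by -0.91 (SE 0.04, adjusted p = 7e-22). Bcl2l1 rose by 1.16 (SE 0.05, adjusted p = 7e-22), while Bcl2l2 stood at 0.15 (adjusted p = 0.083, called when adjusted over the list alone). Of the 11 pro-apoptotic genes 4 rose (Bbc3 0.56, Pmaip1 0.40, Bmf 0.32 and Bax 0.24) and 4 fell (Bik -0.71, Bad -0.36, Bak1 -0.20 and Bid -0.15), against 5 and 4 over the list alone (adjusted p = 0.741). The fall of Bid was lost at equal depth (-0.16) and without replicate 1 (-0.15) or 2 (-0.13) of the control or replicate 2 of the mutant (-0.10). In all, 4828 genes were higher and 4452 lower in the mutant (55.0% of those tested), 793 and 1073 of them at least 2-fold.

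The strongest falls in the C91A mutant outside Bcl2 were Prr19 (-2.95, SE 0.23), Adad2 (-2.37), Chrna9 (-2.36), which encodes a nicotinic receptor subunit, and Nos3 (-2.35), the endothelial nitric oxide synthase. The strongest rises were Acta2 (3.38, SE 0.07), from 9.29 to 97.0 CPM, Acta1 (2.96), Thbs1 (2.73), from 39.5 to 265 CPM, Efemp1 (2.71) and the guidance factor Sema3c (2.63). Of the fibroblast genes 17 of 21 rose and 1 fell (adjusted p = 1.66e-11, 0.00104 estimated). Of the p53 targets 24 of 32 rose and 3 fell (adjusted p = 1.76e-08, 0.00104 estimated, Ptpn14 1.14, Perp 1.12). General pluripotency genes fell in 15 of 16 cases and rose in 1 (adjusted p = 5.58e-08, 0.00104 estimated, Foxd3 -1.93, Dppa5a -0.85). Naive genes fell in 15 of 20 and rose in 1 (adjusted p = 2.82e-06, 0.00104 estimated, Fgf4 -0.98, Nr5a2 -1.13). The untreated C91A line was above wild type for 15 of these 20 naive genes (median 0.29). Nr5a2 was at 23.56 CPM in wild type, 33.71 in that line and 15.43 in the mutant. Endoderm genes rose in 12 of 22 cases and fell in 2 (13 and 2 over the list alone, adjusted p = 0.00022, 0.0265 estimated, Lrp2 1.64). Imprinted genes rose in 20 of 30 cases and fell in 3 (adjusted p = 2.57e-05, 0.00135 estimated, Gnas 0.86). Interferon-stimulated genes fell in 16 of 24 cases and rose in 3 (adjusted p = 0.00966, 0.0265 estimated, Oasl2 -1.07). The untreated C91A line stood above wild type for 23 of these 24 genes (median 1.20), and Oasl2 was at 6.60 CPM in wild type, 21.3 in that line and 10.1 in the mutant. Replication genes, which did not pass after knockout, fell in 21 of 26 cases with no rise (adjusted p = 9.62e-07, 0.0131 estimated, Ccne1 -0.94, Ung -0.63).

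In the C91A mutant, 3 further lists passed camera under the preset correlation but not the estimated one. Germline genes fell in 16 of 27 cases and rose in 2 (Piwil2 -1.15, adjusted p = 0.00534, and adjusted p = 0.213 with an estimated correlation). Cholesterol genes fell in 16 of 25 and rose in 3 (Hsd17b7 -1.01, adjusted p = 0.000628, and adjusted p = 0.101 with an estimated correlation). Glycolysis genes fell in 17 of 28 cases and rose in 3 (Pdk1 -0.98, adjusted p = 7.6e-05, and adjusted p = 0.0594 with an estimated correlation). Ribosomal protein genes, with 21 of 82 up and 3 down (17 and 3 over the list alone), did not pass (adjusted p = 0.329), nor did the MAPK feedback genes (8 up, 7 down, 8 and 8 over the list alone, adjusted p = 0.824). In total 11 of 29 lists passed (12 unadjusted), 8 with the estimated correlation, and fry called 18. Among lists that did not pass, median and mean differed in sign in 5, median and test in 5, and mean and test in 1, against 0, 3 and 3 for the knockout. The latter were the pro-apoptotic, mesoderm and trophoblast lists. The same counts were 4, 4 and 2 for the difference between the alleles, and for the double knockout 2, 3 and 3 against the knockout and 2, 3 and 1 against wild type.

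The 2 BAP1 alleles changed overlapping sets of genes, in comparisons that share no library. Both comparisons include the effect of the drug and of Cre, which can add to the overlap. Of the genes lower after knockout, 3265 (63.9%) were also lower in the C91A mutant against 1348 expected if independent, and of those higher, 3519 (66.6%) were also higher against 1511. Opposite calls numbered 233 and 142 against 1462 and 1394. Across genes, which are not independent replicates, the log2 fold changes had r = 0.730 and rho = 0.722, with a slope of 0.588 of the C91A change on the knockout change. Of the 1771 genes at least 2-fold lower after knockout, such as Zbtb32, 1259 were also lower in the mutant and 21 higher.

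**Figure D3:**
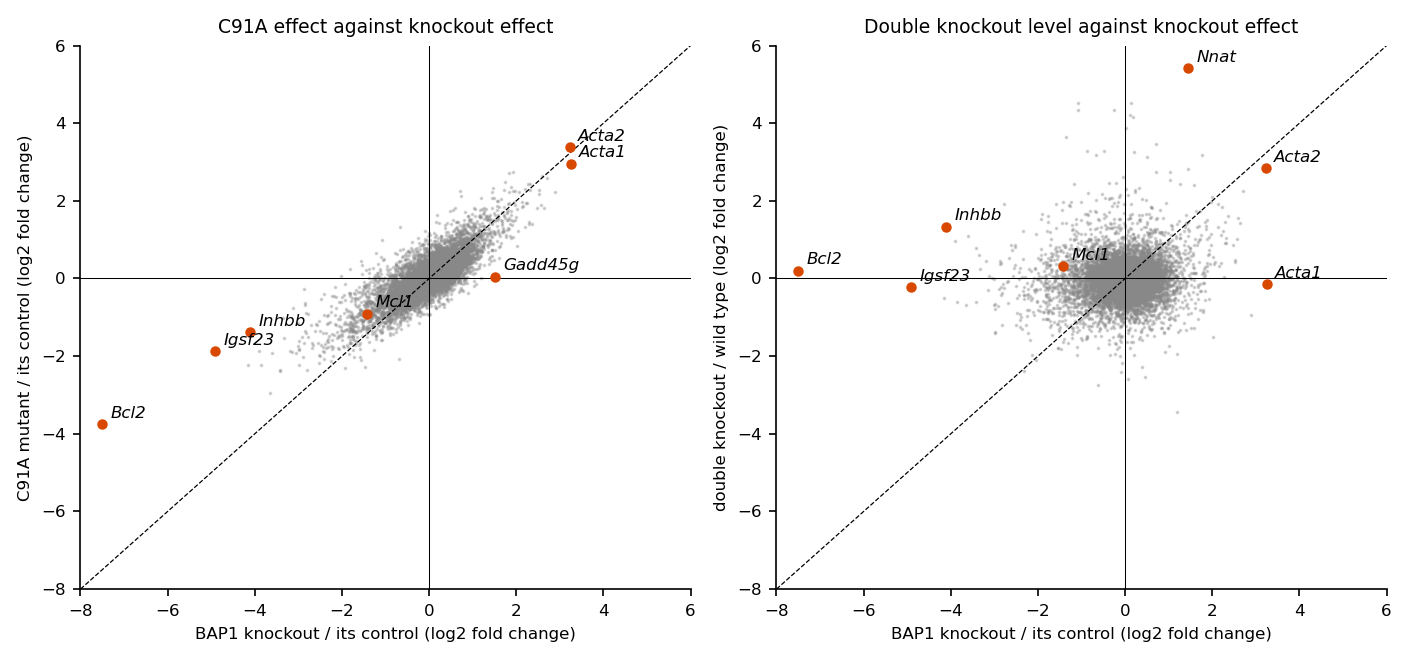
Each dot is a gene with a mean log2 CPM of at least 2. The x axis is its log2 fold change in BAP1 knockout against its control, and the y axis is that in the C91A mutant against its control (left) or in the double knockout against wild type (right), with the dashed line marking equal change. Across all 16875 genes r is 0.730 on the left and 0.105 on the right.

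The size of the change differed between the alleles for many genes, by the test of the difference itself. Bcl2 fell further after knockout than in the C91A mutant (difference -3.74, SE 0.46, adjusted p = 3.2e-08), as did Mcl1 (-0.53, SE 0.06, adjusted p = 2.8e-09), Igsf23 (-3.03, SE 0.54) and Inhbb (-2.72, SE 0.24). For Bcl2, C91A mutant library 1 (5.04 CPM) lay near the knockout libraries, and libraries 2 and 3 (64.0 and 54.9 CPM) lay above them. The difference passed the test without any 1 of these libraries. Mcl1 ended at 533 CPM after knockout and 507 in the C91A mutant, from 1436 and 950 CPM in the untreated lines. Inhbb started at 39.25 and 10.7 CPM. Gadd45g, a stress-inducible gene, had the most positive difference (1.46, SE 0.08, adjusted p = 1.4e-16), followed by Tchh (1.26) and Lbh (1.23). Bcl2l1 rose less (-0.54) and Pmaip1 more (0.46) after knockout. The difference was positive in 2054 genes and negative in 2321, of which 87 and 449 were at least 2-fold, and 6170 genes had an unadjusted p under 0.05. With a minimum fold of 1.5 in the test, 20 and 195 were left.

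Of the lists, 6 of 29 passed the preset test for the difference between the alleles (11 unadjusted), and 0 passed camera with the estimated correlation (6 unadjusted), against 20 with fry. MAPK feedback genes had a lower change after knockout in 15 of 23 cases and a higher one in 2 (16 and 2 over the list alone). The list had adjusted p = 4.23e-09, and adjusted p = 0.0607 with an estimated correlation. Examples were Spry4 (-1.48) and Dusp6 (-1.06), both feedback inhibitors of ERK signalling, and Myc (-1.39). Ribosomal protein genes had a higher change in 52 of 82 cases and a lower one in 1 (57 and 1 over the list alone, Rps20 0.62). Their adjusted p = 3.75e-15 became adjusted p = 0.12 with an estimated correlation. Fibroblast genes had a lower change in 10 of 21 cases and a higher one in 2 (10 and 3 over the list alone). Their adjusted p = 0.00585 also became adjusted p = 0.12 with an estimated correlation. The preset test called 10 lists without replicate 1 of the knockout, of the C91A control or of the C91A mutant.

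The double knockout, which lacks RNF2 as well, did not show the loss of Bcl2. Bcl2 was at 918 CPM (SD 58.0), or 7.59 (SE 0.33, adjusted p = 9.8e-23) above the BAP1 knockout, and 0.20 (SE 0.19, adjusted p = 0.38) from the wild type at 796 (SD 128). That last difference was called with no filter on low counts (0.19) and in a fit of the 2 groups alone (0.21). Mcl1 was at 1608 CPM (SD 51.4), 1.59 (SE 0.04, adjusted p = 1e-29) above the knockout and 0.31 (SE 0.04, adjusted p = 9.7e-09) above wild type at 1293 (SD 86.8). Against the knockout Bcl2l1 (-0.35), Bcl2l2 (-0.41), Bbc3 (-0.98), Bax (-0.54) and Pmaip1 (-0.48) fell, and Bcl2l11 (0.38), Hrk (0.65), Bmf (0.28) and Bid (0.17) rose. The rise of Bid was lost without replicate 2 (0.15) or 3 (0.14) of the knockout or replicate 3 of the double knockout (0.15). No untreated double knockout cells were used here, so differences between lines are part of every double knockout comparison. Whether wild type received the drug is not given in the sources used here, so a drug effect is not separated from the comparison with wild type.

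The double knockout had 5500 genes higher and 5171 lower than the BAP1 knockout, and 2197 and 543 of them differed at least 2-fold. Among genes with a mean log2 CPM of at least 2, the highest named after Bcl2 were Igsf23 (4.67, SE 0.38) and the endocytic receptor gene Cubn (4.34, SE 0.17), from 1.17 to 24.6 CPM. Next came the meiotic genes Stra8 (4.28, SE 0.12), from 2.95 to 56.4 CPM, and Sycp1 (4.17, SE 0.21). Cubn was already low in the untreated knockout line, at 1.27 CPM against 17.2 in wild type, so line differences are part of its change. The lowest were Lhx9 (-4.15, SE 0.19), from 17.4 to 0.970 CPM, Acta1 (-2.95, SE 0.14), the class I antigen gene H2-K2 (-2.89), Myl3 (-2.86), a myosin light chain, and Syp (-2.57), which encodes synaptophysin. Acta2, the other actin gene, was at 49.1 CPM against 44.9, a change of 0.13 that did not pass (adjusted p = 0.075).

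Genes that had fallen after BAP1 knockout were mostly higher in the double knockout. Of 5109 genes lower after knockout, 3871 (75.8%) were higher in the double knockout than in the knockout, and of 5283 higher genes 4064 (76.9%) were lower. Both comparisons contain the knockout libraries, which alone makes them look opposite. Across genes r was -0.746 and the covariance -0.602. In 20 simulations with no change between groups r was -0.605 and the covariance -0.0293. That simulated r is of noise alone, so it does not give the part of the observed r that comes from sharing. The covariances can be compared, and that from shared noise between libraries was small. A shift common to all knockout libraries would also enter both comparisons with opposite signs, and was not simulated. Against wild type, which shares no library with the knockout comparison, the lowered genes had a median of -0.02 in the double knockout (1298 higher, 1536 lower, 2275 not called). The 1771 genes lowered at least 2-fold had a median of -1.62 after knockout, -0.972 in the C91A mutant and -0.030 in the double knockout against wild type. The 812 genes raised at least 2-fold had medians of 1.38, 1.13 and 0.384, and 368 of them, such as Acta2, were above wild type. Genes in the same direction in both comparisons numbered 132 (lower) and 193 (higher), the latter 117 without replicate 3 of the knockout.

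**Figure D4:**
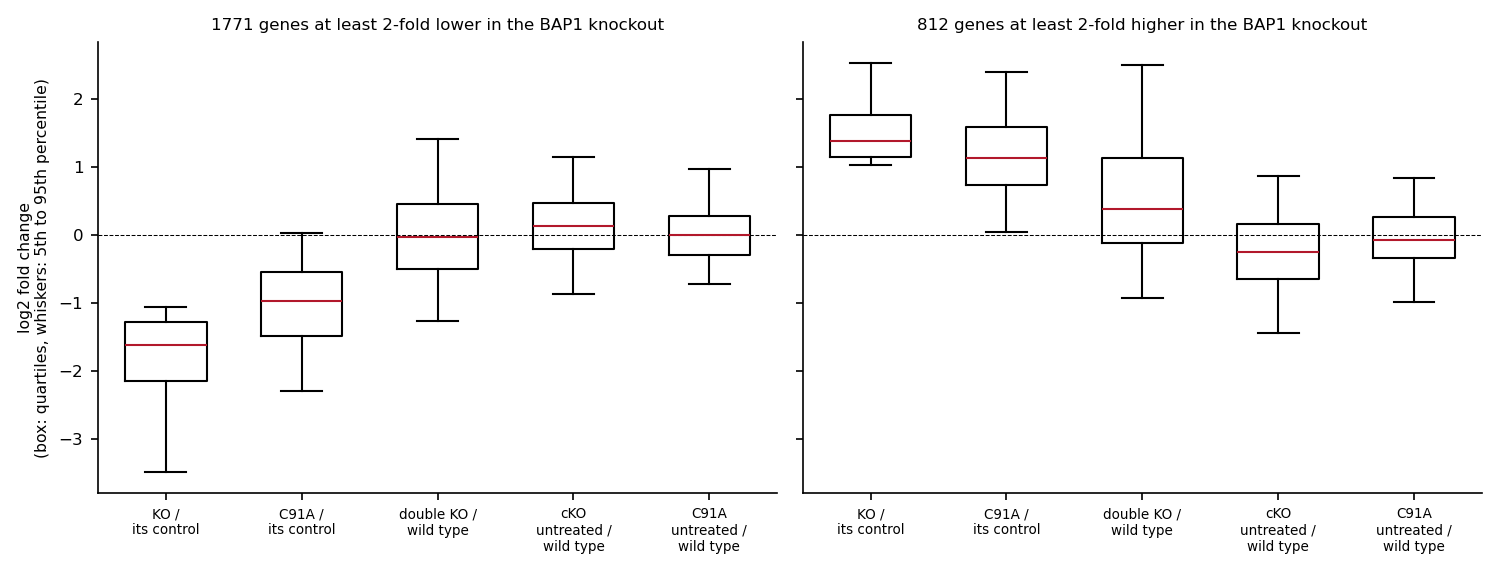
Log2 fold changes of the 1771 genes lowered and the 812 genes raised at least 2-fold by BAP1 knockout, in that comparison, in the C91A mutant, and in the double knockout and the 2 untreated lines against wild type; boxes are quartiles and whiskers run from the 5th to the 95th percentile. The lowered genes have medians of -1.62, -0.972, -0.030, 0.131 and -0.008, and the raised genes 1.38, 1.13, 0.384, -0.251 and -0.074.

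Germline and early embryonic genes rose in the double knockout above both the knockout and wild type. All 18 two-cell-like genes, normally on in the early mouse embryo, were higher than in the knockout (median 4.25, or 4.07 with the 3 genes at 0 in a group set to their bound, adjusted p = 1.76e-06, 0.0016 estimated). Examples were Usp17la (4.08) and Usp17le (3.13), whose near-identical copies share reads. Germline genes rose in 23 of 27 cases and fell in 1 (23 and 2 over the list alone, adjusted p = 7.3e-12, 0.00714 estimated). Sohlh2 (2.90) went from 13.4 to 99.5 CPM, Piwil2 (2.45) from 17.9 to 97.9, and Mael rose by 2.97. Of 35 HOX genes, the patterning genes silenced by Polycomb in these cells, 32 rose and 0 fell by edgeR's test (adjusted p = 1.76e-06, 0.0016 estimated). Hoxb13 (3.05) went from 1.88 to 15.8 CPM, and Hoxd13 stood at 3.87. Against wild type, all 35 HOX genes (median 3.20, adjusted p = 8.91e-16, 2.46e-05 estimated) and all 18 two-cell-like genes (median 4.24, adjusted p = 1.18e-09, 0.000164 estimated) were higher. Of the 27 germline genes 22 were higher and 1 lower than in wild type (23 and 1 over the list alone, adjusted p = 2.78e-14, 0.0034 estimated).

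Pluripotency genes were mostly higher in the double knockout than in the knockout. Of the 16 general genes 12 rose and 2 fell (adjusted p = 8.83e-05, 0.0074 estimated, Foxd3 3.66, Dppa2 1.97), and of the 20 naive genes 15 rose and 2 fell (16 and 2 over the list alone, adjusted p = 3.68e-06, 0.0016 estimated, Klf4 1.21, Gbx2 2.60). The p53 targets fell in 23 of 32 cases and rose in 3 (3 and 24 over the list alone, adjusted p = 1.22e-06, 0.00341 estimated, Perp -1.26, Zmat3 -0.80). Interferon-stimulated genes rose in 16 of 24 cases and fell in 2 (adjusted p = 0.00998, 0.0345 estimated, Oasl2 1.72). Cholesterol genes fell in 16 of 25 and rose in 3 (3 and 19 over the list alone, adjusted p = 2.57e-05, 0.0499 estimated, Insig1 -1.14). The fibroblast genes did not differ from other genes as a set (10 up, 6 down, 12 and 6 over the list alone, adjusted p = 0.267). Ribosomal protein genes fell in 69 of 82 cases and rose in 5 (5 and 71 over the list alone, Rpl4 -0.66, adjusted p = 3.64e-12, and adjusted p = 0.0521 with an estimated correlation).

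By camera, 4 further lists passed under the preset correlation but not the estimated one. Endoderm genes rose in 16 of 22 cases and fell in 4 (Col4a1 1.02, adjusted p = 0.00227, and adjusted p = 0.0521 with an estimated correlation). The untreated knockout line was already below wild type for 18 of these 22 genes (median -1.28). Against wild type the double knockout had 6 higher and 6 lower (9 and 7 over the list alone, camera adjusted p = 0.621). Col4a1 was at 427.1 CPM in wild type, 88.04 in that untreated line, 186.5 in the knockout and 377 in the double knockout. Formative genes rose in 12 of 17 and fell in 3 (Tcf15 2.60, adjusted p = 0.00649, and adjusted p = 0.0559 with an estimated correlation). Mitotic genes fell in 17 of 26 cases and rose in 1 (Nusap1 -0.58, adjusted p = 0.00166, and adjusted p = 0.0521 with an estimated correlation). MAPK feedback genes rose in 15 of 23 and fell in 6 (16 and 6 over the list alone, Spry4 2.32, adjusted p = 0.00747, and adjusted p = 0.19 with an estimated correlation). In total 13 lists passed (15 unadjusted), 8 with the estimated correlation, and fry called 26.

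**Figure D5:**
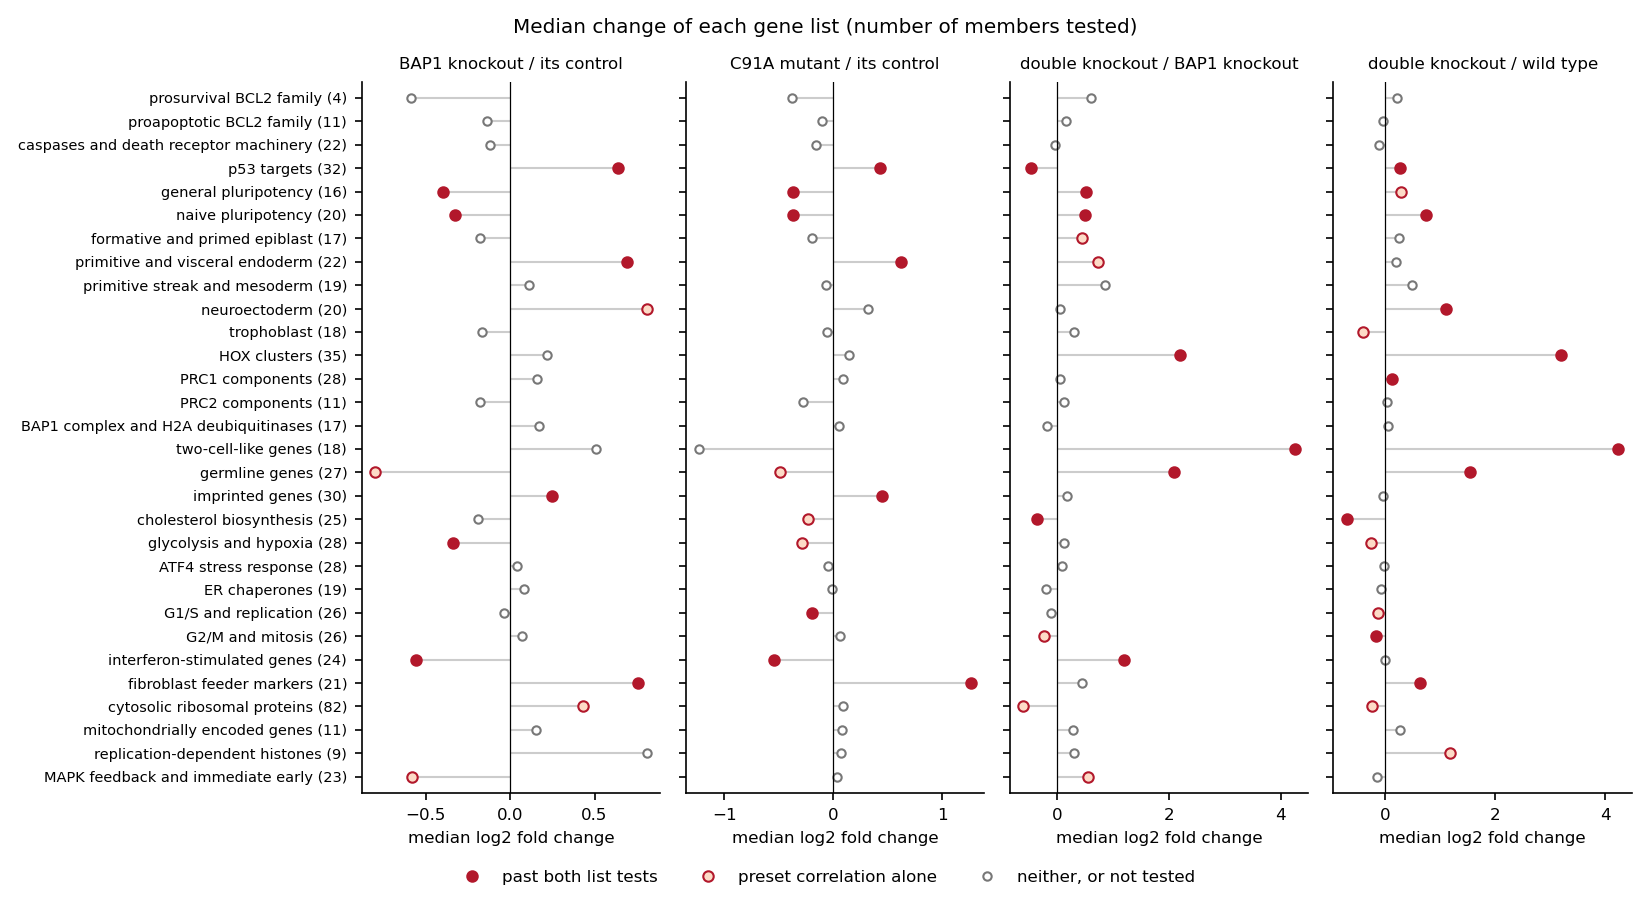
Median log2 fold change of the tested members of 30 gene lists in 4 comparisons; filled dots passed the list test with both the preset and the estimated correlation, pale dots with the preset correlation alone, and open dots with neither or were not tested. The HOX list lies at 2.20 in the double knockout against the knockout and at 3.20 against wild type.

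Against wild type the double knockout had 4422 genes higher and 4568 lower, 1079 and 474 of them at least 2-fold. Among genes with a mean log2 CPM of at least 2, the highest were Nnat (5.41, SE 0.12), an imprinted gene that went from 1.08 to 46.1 CPM, Calcoco2 (4.53) and Tex13b (4.51), and the lowest were Myl3 (-3.43), Enpp2 (-2.73) and Plvap (-2.59). Nnat was also at 24.3 CPM in the untreated knockout line. Naive pluripotency genes rose in 17 of 20 cases and fell in 1 (adjusted p = 2.46e-14, 2.46e-05 estimated), with Klf4 (1.75) from 105 to 354 CPM and Jam2 (2.32) from 29.7 to 148. The untreated knockout line was also above wild type for 17 of these 20 genes and below for 2 (median 0.65, against 0.73 here), with Klf4 at 248 CPM. Neuroectoderm genes rose in 16 of 20 cases and fell in 2 (adjusted p = 2.36e-05, 0.00635 estimated, Zic1 5.04, Ncam1 1.45). The untreated knockout line was also above wild type for 10 of these 20 genes and below for 2 (12 and 2 over the list alone). Its median was 0.37, against 1.1 here (camera adjusted p = 0.0119, 0.0865 estimated). Ncam1 was at 8.092 CPM in wild type, 19.97 in that line and 21.94 in the double knockout. Cholesterol synthesis genes fell in 22 of 25 cases and rose in 1 (1 and 23 over the list alone, adjusted p = 1.54e-15, 0.00137 estimated), with Mvd (-1.48) from 253 to 90.9 CPM.

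Among smaller shifts against wild type, p53 targets rose in 24 of 32 cases and fell in 3 (adjusted p = 2.45e-06, 0.0034 estimated). Fibroblast genes rose in 15 of 21 and fell in 3 (adjusted p = 7.89e-06, 0.0053 estimated, Acta2 2.85). PRC1 genes rose in 14 of 28 cases and fell in 5 (adjusted p = 0.0165, 0.036 estimated). Mitotic genes fell in 19 of 26 and rose in 1 (adjusted p = 0.000122, 0.0261 estimated, Aurkb -0.49). The untreated knockout line also differed from wild type for the p53 targets (18 up, 1 down, median 0.18 against 0.27 here) and the mitotic genes (1 up, 15 down, 1 and 16 over the list alone, median -0.15 against -0.18). The mitotic list had adjusted p = 0.0036 there, and adjusted p = 0.0865 with an estimated correlation. Another 6 calls were lost with the estimated correlation, among them general pluripotency (9 up, 3 down, preset 0.0165, adjusted p = 0.0657), trophoblast (3 up, 13 down, preset 0.0046, adjusted p = 0.32) and glycolysis (6 up, 16 down, preset 0.0119, adjusted p = 0.197). The same held for replication (1 up, 17 down, 2 and 17 over the list alone, preset 0.00238, adjusted p = 0.0796), ribosomal proteins (4 up, 44 down, preset 3.99e-05, adjusted p = 0.242) and histones (7 up, 0 down by edgeR's test, 8 and 0 over the list alone, preset 0.0165, adjusted p = 0.0683). The histone list was also lost in the preset test without replicate 2 of wild type (adjusted p = 0.0686) or replicate 1 of the double knockout (adjusted p = 0.0663). In total 16 of 29 lists passed (18 unadjusted), 10 with the estimated correlation, and fry called 27.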

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

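In this part, the tests for fibroblast cells and for scaling, the tests at equal depth, those on genes lowered by the mean of both alleles, and the other splits of the libraries were chosen after the results were seen. The results below stood out because the change after BAP1 knockout and that in the C91A mutant differed by the test of the difference, which was positive for 2054 genes and negative for 2321. Among named genes the difference was -3.74 for Bcl2, -3.03 for Igsf23, -2.72 for Inhbb, -2.04 for Halr1, -1.92 for Zbtb32, -1.07 for Bap1, -1.07 for Chrna9, -1.05 for Adad2, -0.87 for Efemp1, -0.81 for Thbs1 and -0.53 for Mcl1. It was 1.46 for Gadd45g, 1.26 for Tchh, 1.23 for Lbh, 0.81 for Cdh2 and 0.65 for Lhx9. For Bap1 it reflects a lower level in the untreated C91A line, 88.9 CPM, than in the mutant, 165 CPM. For Mcl1 the end levels were alike, 533 CPM after knockout and 507 in the mutant, and the untreated lines differed (1436 and 950 CPM). Inhbb also started from different levels (39.25 and 10.7 CPM). Among lists, the median difference was 0.14 for p53 targets, 0.35 for neuroectoderm, 0.12 for replication, -0.38 for fibroblast genes, 0.34 for ribosomal proteins and -0.43 for MAPK feedback genes, and each call was lost with an estimated correlation, with adjusted p = 0.125, 0.125, 0.125, 0.12, 0.12 and 0.0607 in that order.

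The C91A mutant libraries kept different amounts of Bcl2, 0.89%, 11.27% and 9.67% of the control level. Cells that had not recombined could bring Bcl2 back in libraries 2 and 3, and would then bring back other lowered genes by a like share; over 317 such genes the median excess in those libraries was 3.85% of the control level (95% interval 1.72 to 5.77), an interval that holds 4.83%, which is 0.5 of the excess of Bcl2, so this stays open as a partial source. The same cells would also pull the 372 raised genes toward the control, but these lay farther from it in libraries 2 and 3 (median -3.96%, -5.78 to -1.96). This argues against such cells as the source of all the residual Bcl2 only if the cultures were otherwise alike, since 1 library was set against 2. A difference between the cultures in how far the response had gone was not tested.

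Fibroblast-type genes such as Acta2, Tagln and Thbs1 rose in both BAP1 comparisons. Feeder fibroblasts would bring their matrix transcripts as well. The gains in this paragraph are in CPM scaled by the library total alone, without the TMM factor used elsewhere. Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn together gained 18.9 CPM after knockout against 346.8 CPM for Acta2, Tagln and Thbs1, or 5.45% (32.0 against 669.9 CPM in the C91A mutant, 4.78%). All other tested members of the list, of which Fn1 alone gained 887.7 and 267.1 CPM, gained 287.5% and 98.2% as much as those 3 genes. With the TMM factor Fn1 went from 1840 to 3000 CPM after knockout and from 1570 to 1970 in the C91A mutant. The gains and shares therefore depend on the scale. No profile of such cells was measured here, so fibroblasts stay open as a source. Depth is argued against by the 15 members called after knockout and called again at equal depth (16 of 17 in the C91A mutant). A wrong scaling would move all genes alike, and is argued against by the difference of the list from all other genes (adjusted p = 0.00422 and 0.00104 with an estimated correlation). A change of the stem cells themselves after loss of BAP1 activity is another candidate explanation, and 4-hydroxytamoxifen and Cre cannot be separated from it in this design.

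The knockout lowered more genes at least 2-fold than the C91A mutation did, 1771 against 1073, a ratio of 1.65. The lower depth of the knockout libraries is argued against by a ratio of 1.64 at equal depth (1453 against 885). In the 1770 genes lowered in the knockout besides Bcl2 the median difference was -0.70 (-0.73 to -0.67). Genes chosen for their fall in the knockout favour a larger change there, so genes were also chosen by the mean change of the 2 alleles. In these 1517 genes the median difference was -0.52 (-0.56 to -0.47), and in 1072 genes lowered in the mutant it was -0.12 (-0.18 to -0.08). Unrecombined cells in the mutant, at the largest share that Bcl2 allows (11.27%), would give -0.33 in the 1517 genes, outside the interval observed, which argues against them as the source of all of the difference and leaves them open as a source of part. In the same genes the untreated C91A line, with its low Bap1 count, had a median of 0.02 against wild type (-0.01 to 0.05). These genes were chosen partly by their change against that line, so genes already low there tend to be left out. The 1771 genes chosen by the knockout comparison alone had a median of -0.008 there, which argues against a general shift already present in that line. Single genes could differ, as Mcl1 did (-0.45, SE 0.04). The 1517 genes had a median of 0.13 in the untreated knockout line. A real difference between absence and inactivity of BAP1 stays open, as do differences between the 2 lines, which each allele has to itself.

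Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. The real split and the highest of the others called 10392 and 0 genes for the knockout, 9280 and 0 for C91A, 10671 and 0 for double knockout against knockout, 8990 and 0 against wild type, 6633 and 0 for the untreated knockout line and 4664 and 0 for the untreated C91A line, by edgeR's test, with 1 split as large in each, the real one itself. For lists under the preset correlation the pairs were 12 and 11 (1 split as large, again counting the real one), 11 and 13 (3), 13 and 13 (2), 16 and 15 (1), 12 and 11 (1), and 13 and 9 (1). Every other split of these 6 comparisons mixes libraries of both groups on each side. It keeps part of the real difference and adds the rest to the spread. The counts of genes and lists in other splits are therefore no chance reference for the real ones. With the estimated correlation other splits of these 6 comparisons called 0 lists by camera. For the difference of the 2 effects, 2 of 30 splits called as many genes (4375, highest other 7488) and 18 of 30 as many lists (6, highest other 14). Of the others, 26 called 0 genes by edgeR's test. These splits also mix or exchange libraries of the groups, so their counts are no chance reference either, and chance was not excluded by them. The split with 7488 pairs the real knockout groups with the C91A groups nearly exchanged, which adds the 2 effects and reflects a structure of the samples.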

How the results depend on the processing

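In this part, the authors' size factors and thinning to equal depth were chosen after the data were seen. No paired analysis was possible because the labels give no replicate numbers, and the planned pseudocount alternative was not run since the files hold counts. No result reversed. Counts and medians moved in 45 of 651 cases, list tests weakened in 26 of 673 (24 with an estimated correlation and 2 on leaving out a library), and named genes weakened in 233 and strengthened in 4 of 6769, 193 of the former against a minimum fold. A count is said to have moved when it changed more than 1.5-fold, and a median when it changed by more than 1 SD. Within that tolerance DESeq2, limma-voom, other size factors, equal depth and fitting the compared groups alone left all counts and medians in place.

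Tested against a minimum fold of 1.5, which asks for larger changes by construction, genes higher and lower numbered 1081 and 1702 for BAP1 knockout, 964 and 971 for C91A, 20 and 195 for the difference of the 2 effects, 2084 and 996 for double knockout against knockout, 1007 and 610 against wild type, 262 and 323 for the untreated knockout line and 120 and 62 for the untreated C91A line. The overlaps of knockout and C91A became 568 (both higher), 751 (both lower), 1 (knockout lower, C91A higher) and 1 (the opposite). Of genes lower after knockout 1174 were higher and 0 lower in the double knockout by edgeR's test, and of those higher 555 were lower and 18 higher.

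Camera with the estimated correlation called 0 lists for the difference of the effects (6 unadjusted), 8 for double knockout against knockout, 10 against wild type, 6 for the untreated knockout line and 3 for the untreated C91A line; it allows for genes of a list varying together. Fry, which compares no list with other genes, called 24 for knockout, 18 for C91A, 20 for the difference, 26 for double knockout against knockout, 27 against wild type and 20 for the untreated knockout line. On leaving out 1 library the lists called for the difference ranged from 6 to 10 (10 without replicate 1 of the knockout, of the C91A control or of the C91A mutant), and the genes higher in both knockout and double knockout from 117 (without knockout replicate 3) to 150. The median against wild type of genes higher after knockout was -0.021 with no filter on low counts and ranged from -0.020 (without wild type replicate 3) to -0.008 on leaving out a library, against -0.010; the cause was not tested. Leaving out a library of the 4 groups left the genes lower with both alleles at 3000 to 3173 and those higher at 3206 to 3455. In simulations at these depths with few genes changed, edgeR recovered 68.8% of 1.5-fold changes, so smaller changes can be missed. Where many genes are called the adjusted threshold is looser, so that share does not give the power of the comparisons here.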

Other observations

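The untreated lines differed from wild type. In the untreated knockout line 3126 genes were higher and 3507 lower, 331 and 406 of them at least 2-fold. Endoderm genes fell in 18 of 22 cases with 0 rises by edgeR's test (1 and 18 over the list alone; median -1.28; adjusted p = 3.2e-16; 0.000239 with an estimated correlation), with the visceral endoderm receptor gene Cubn at 1.27 CPM against 17.2 in wild type. Naive pluripotency genes rose in 17 of 20 cases and fell in 2 (median 0.65; adjusted p = 3.2e-16; 2.22e-05 estimated), with Klf4 at 248 CPM against 105, and fibroblast genes fell in 16 of 21 and rose in 1 (1 and 17 over the list alone; adjusted p = 1.48e-08; 0.00194 estimated). The p53 targets (18 up, 1 down; adjusted p = 2.62e-05; 0.0102 estimated), general pluripotency genes (11 up, 2 down; adjusted p = 0.000214; 0.0113 estimated) and HOX genes (13 up of 35, 0 down by edgeR's test; median 0.90, or 0.89 with 2 genes at 0 in a group set to their bound; adjusted p = 0.0039; 0.0255 estimated) were also higher. The other 6 of the 12 lists called were lost with the estimated correlation.

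In the untreated C91A line 2261 genes were higher and 2403 lower than in wild type, 230 and 147 of them at least 2-fold. Interferon-stimulated genes, the antiviral response, rose in 23 of 24 cases with 0 falls by edgeR's test (median 1.20; adjusted p = 1.69e-25; 1.48e-06 estimated), with Isg15 at 3.30 and Irf7 at 2.69 on the log2 scale, genes chosen after their values were seen. Naive pluripotency genes rose in 15 of 20 cases (median 0.29; adjusted p = 1.92e-11; 7.62e-05 estimated) and endoderm genes fell in 13 of 22 and rose in 2 (3 and 13 over the list alone; adjusted p = 2.78e-05; 0.0284 estimated), and the other 10 of the 13 lists called were lost. The fall of interferon-stimulated genes in the C91A mutant therefore started from a control above wild type, whereas in the untreated knockout line 4 were higher and 7 lower than in wild type (5 and 7 over the list alone; adjusted p = 0.516). Bap1 was lower in this line (88.9 CPM against 178) and Nnat, an imprinted gene, was higher in both untreated lines (24.3 and 11.5 CPM against 1.08).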
